A study of Mus musculus with 8 samples.

How the data were processed

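Total RNA from the livers of 8 mice aged 2 days was measured on Affymetrix expression arrays, with 1 array per mouse. Per the labels, 4 mice lacked Mfp2 and 4 were wild type, and each group has replicates 1 to 4. Mfp2, the multifunctional protein 2 of peroxisomes, is encoded by the gene Hsd17b4. The RNA was extracted with Trizol and labelled with biotin, per the labels' protocols. The design text speaks of 4 knockout and 4 wild type mice, so each array was taken as a separate animal.

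The deposited table holds log2 values that the authors made with RMA, per the submitters' processing notes. RMA is a method that corrects background, gives all arrays the same distribution of probe values and summarises the probes of a set into 1 value on the log2 scale. The software, its version and its settings are not given in the sources used here. The log2 scale was read from the values, which ran from 1.12 to 13.7, with medians between 3.68 and 3.73 on the 8 arrays. Because the arrays were brought to a shared probe distribution before deposit, a change in the total amount of mRNA per liver cannot be seen, and differences of dim probe sets may be understated. Arrays give no read depth. Their number, 4 against 4, limits the precision. Transcripts of all liver cells were measured together, so blood-forming and other cells present in newborn liver contribute to each value.

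The table holds 45101 probe sets. The 64 array controls were left out of all tests but the RNA quality check, which left 45037. The array annotation pairs 34945 of these with 1 gene and 932 with several, and 9160 are not listed in it and are unnamed here. Gene symbols were checked through Entrez identifiers against the gene table of the mouse assembly GRCm38.p6, in which the identifiers of 34741 probe sets were found. That table was used only for names and for which genes neighbour each other, since the build behind the array is not given in the sources used here. The probe set with the highest mean over all 8 arrays stood for its gene, which gave 18194 genes.

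Knockout livers were compared with wild type livers with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate). P-values were adjusted by the Benjamini-Hochberg method over the 45037 probe sets, with a threshold of 0.05. All differences are knockout minus wild type on the log2 scale, given with the standard error (SE) of the fit, and group means are given with the standard deviation (SD) over 4 livers. The fit was tested on simulated data before use, in the same comparison of knockout against wild type. The 45037 simulated probe sets had the real arrays' means and the variances that eBayes estimated. At a log2 change of 1 it recovered 86.6% of changed probe sets, at a change of 0.5 it recovered 17.9%, and at a change of 2 all were recovered. Of the calls, 4.23% were false, and with no change 0 probe sets were called. The simulated values were independent, with no correlation between genes and no batch or sex difference. These shares therefore need not hold for the real arrays.

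39 gene lists (pathways and cell types) were fixed before the data were examined, with 642 entries, of which 576 had a probe set under the listed symbol and are called measured. Others may be on the array under an older symbol, so an entry not found is not known to be absent. A list was tested with limma's camera against all other genes where at least 4 members were measured, which left 38 lists, with the correlation between genes preset to 0.01 and adjustment over the 38 lists. camera was repeated with the correlation estimated from the data. For each list the members past the threshold were counted over all probe sets and adjusted over the list alone. The mean of each list per liver was also compared with an exact permutation test, two-sided, for which 4 against 4 livers allow no p below 0.0286. The choice of PPARalpha, peroxisomal and cholesterol lists followed from what is known of this knockout, so that choice is not independent of the published study, while their members came from textbook knowledge and not from these arrays.

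The genes named were set by a rule fixed with the lists. It takes Hsd17b4, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose groups did not overlap, and up to 4 members past the threshold of each list, or the member with the lowest p where none passed. Clone names and predicted genes were skipped among the 24. Any other gene named was chosen after its values were seen, and is said to be.

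Replicate numbers are shared by the groups but no label ties them to litters or batches, so the fit has no block. Alternatives changed 1 choice at a time: a filter leaving out probe sets below the median of all means, quantile normalization again, median centring per array, trended and robust variance estimation, array weights, the replicate block, the erythroid marker mean or the mean of the Y-linked genes as a covariate, the mean of all probe sets of a gene, no probe sets named _x_at or _s_at, at least a 1.5-fold difference, an adjusted p under 0.01, the estimated correlation in camera, and leaving out each array in turn. 5 further alternatives were chosen after seeing the data. They were livers of one sex-chromosome pattern only (2 settings), a block for replicates 1 and 2 against 3 and 4, and each of these 2 sets of arrays alone. A value not past its threshold was taken to have no direction, so that a change of sign was counted only where 1 of the 2 fits passed.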

Results

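Gene expression was measured in the livers of 8 mice aged 2 days, 4 with a knockout of Mfp2 and 4 wild type. Mfp2 is a peroxisomal enzyme of the chain-shortening of very long chain and branched fatty acids and of bile acid precursors. The question was which liver transcripts differ in newborn mice that lack it. Pearson correlations between arrays, over all probe sets, lay between 0.983 and 0.994 within groups and between 0.976 and 0.989 across groups. The labels do not give the sex of the mice. Xist, the RNA of the inactive X chromosome, was high and Y-linked transcripts were low in knockout 1, knockout 2 and wild type 3, and the reverse held in the other 5 livers. The 3' minus 5' value of the actin control, a sign of RNA quality, averaged 0.704 ± 0.122 (SD, n = 4) in knockout and 0.619 ± 0.069 in wild type arrays, with an exact permutation p = 0.343. That of the GAPDH control averaged -0.083 ± 0.118 and -0.068 ± 0.044, with an exact permutation p = 0.886. A comparison by replicate number pooled the genotypes and did not test each alone. In it the arrays of replicates 1 and 2 differed from those of replicates 3 and 4 at 170 probe sets past the threshold in limma. Because each of these 2 sets holds 2 livers per genotype, differences are also given within each set. Sex is not balanced there. In replicates 1 and 2 both knockout livers were high in Xist and 0 of the wild type livers were, so that genotype and sex cannot be told apart within that set, and in replicates 3 and 4 a single wild type liver was high in Xist.

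Transcripts of the targeted gene were low in all 4 knockout livers. Hsd17b4, the gene of Mfp2, averaged 3.84 ± 0.45 (SD, n = 4) in knockout and 8.50 ± 0.40 in wild type livers. The difference was -4.66 ± 0.25 (SE), a 25.3-fold lower level, with a limma adjusted p of 0.000100. The knockout mean lies near the array medians of 3.68 to 3.73 and is not shown to be above background, so the fold can be an underestimate. Knockout values lay between 3.25 and 4.29 and wild type values between 8.15 and 8.97, so each array matched its label. A second probe set of the gene fell by 5.96 on the log2 scale, which can be an underestimate too, since its knockout mean of 2.13 lies below the median of each array. Where the probes lie relative to the deleted part is not stated in the sources used here. In replicates 1 and 2 alone the difference was -4.42, and in replicates 3 and 4 alone it was -4.91.

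The genes past the threshold included 10 of the 20 measured genes of the cholesterol synthesis and uptake list, higher in the knockout, and 7 of 24 cell cycle genes and 4 of 15 erythroid markers, lower in the knockout. In all, 343 probe sets passed the threshold in limma, 89 higher and 254 lower in the knockout. Per gene, 209 genes passed, 56 higher and 153 lower. In each of the 209 the 4 knockout values lay all above or all below the 4 wild type values. Such separation was seen in 8.61% of all genes, against 2.86% by chance. At an unadjusted p under 0.05 there were 5274 probe sets, where chance gives 2252. Of the 209 genes 204 had an adjusted p above 0.02, so most calls lay close to the threshold.

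The 12 largest rises among genes whose groups did not overlap ran from 2.41-fold to 7.01-fold, with limma adjusted p between 0.00273 and 0.0499. Slc4a9, an anion exchanger, rose by 2.81 ± 0.41 (SE). Abcb1a, a drug efflux pump of the cell membrane, rose by 2.51 ± 0.20, from 4.58 ± 0.43 (SD, n = 4) to 7.09 ± 0.18. Cxcl10, an interferon-induced chemokine, rose by 2.17 ± 0.41 and Defb1, a beta-defensin, by 1.88 ± 0.32. Gsta4 and Gstt2, which encode glutathione S-transferases, rose by 1.85 ± 0.17 and 1.29 ± 0.13. Slc51b, a subunit of the basolateral bile acid exporter, rose by 1.27 ± 0.11. The other 5 were the cholesterol synthesis genes Msmo1, Cyp51, Fdps, Lss and Nsdhl.

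Beyond Hsd17b4, the 12 largest falls ran from 2.39-fold to 6.64-fold, with limma adjusted p between 0.0204 and 0.0480. Dio1, the type 1 iodothyronine deiodinase that converts thyroid hormone, fell most, by 2.73 ± 0.44 (SE), from 5.89 ± 1.04 (SD, n = 4) in wild type to 3.16 ± 0.39 in knockout livers. That knockout mean lies below the median of each array, so its fold can be an underestimate. Genes known from red blood cell precursors were among the rest. Trim10 fell by 1.32 ± 0.21, Dmtn, a protein of the red cell membrane skeleton, by 1.26 ± 0.17, and Hbb-bh1, an embryonic globin, by 1.32 ± 0.19. Plek2 fell by 1.78 ± 0.32, Tmcc2 by 1.28 ± 0.20, Apol8 by 1.75 ± 0.21 and Mmd2 by 1.47 ± 0.21, with 2 of the 3 probe sets of Mmd2 lower. Egln3, an oxygen-sensing prolyl hydroxylase, fell by 1.45 ± 0.17, and Mthfd2, a mitochondrial folate enzyme, by 1.27 ± 0.15. Eef2k, the kinase of elongation factor 2, fell by 1.32 ± 0.17 and Dscc1, a factor of sister chromatid cohesion, by 1.31 ± 0.24.

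The number of calls depended on single arrays. Where 209 genes passed with all arrays, 286 passed without wild type 2, 167 without knockout 2, 5 without knockout 4 and 5 without wild type 4. There were 7 without wild type 3, 22 without knockout 3, 89 without wild type 1 and 108 without knockout 1. The 209 genes kept their direction in each of these fits. Leaving out an array could not change it, since their groups did not overlap, so this is no sign of stability. Hsd17b4, Abcb1a, Gsta4 and Slc51b were the 4 named genes that passed without each of the 8 arrays in turn, with a highest limma adjusted p of 0.0371. With the 2 sets of arrays as a block 302 genes passed, 205 of them among the 209. In replicates 1 and 2 alone 3 genes passed, and in replicates 3 and 4 alone 264 passed, 99 of them among the 209.

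**Figure D1:**
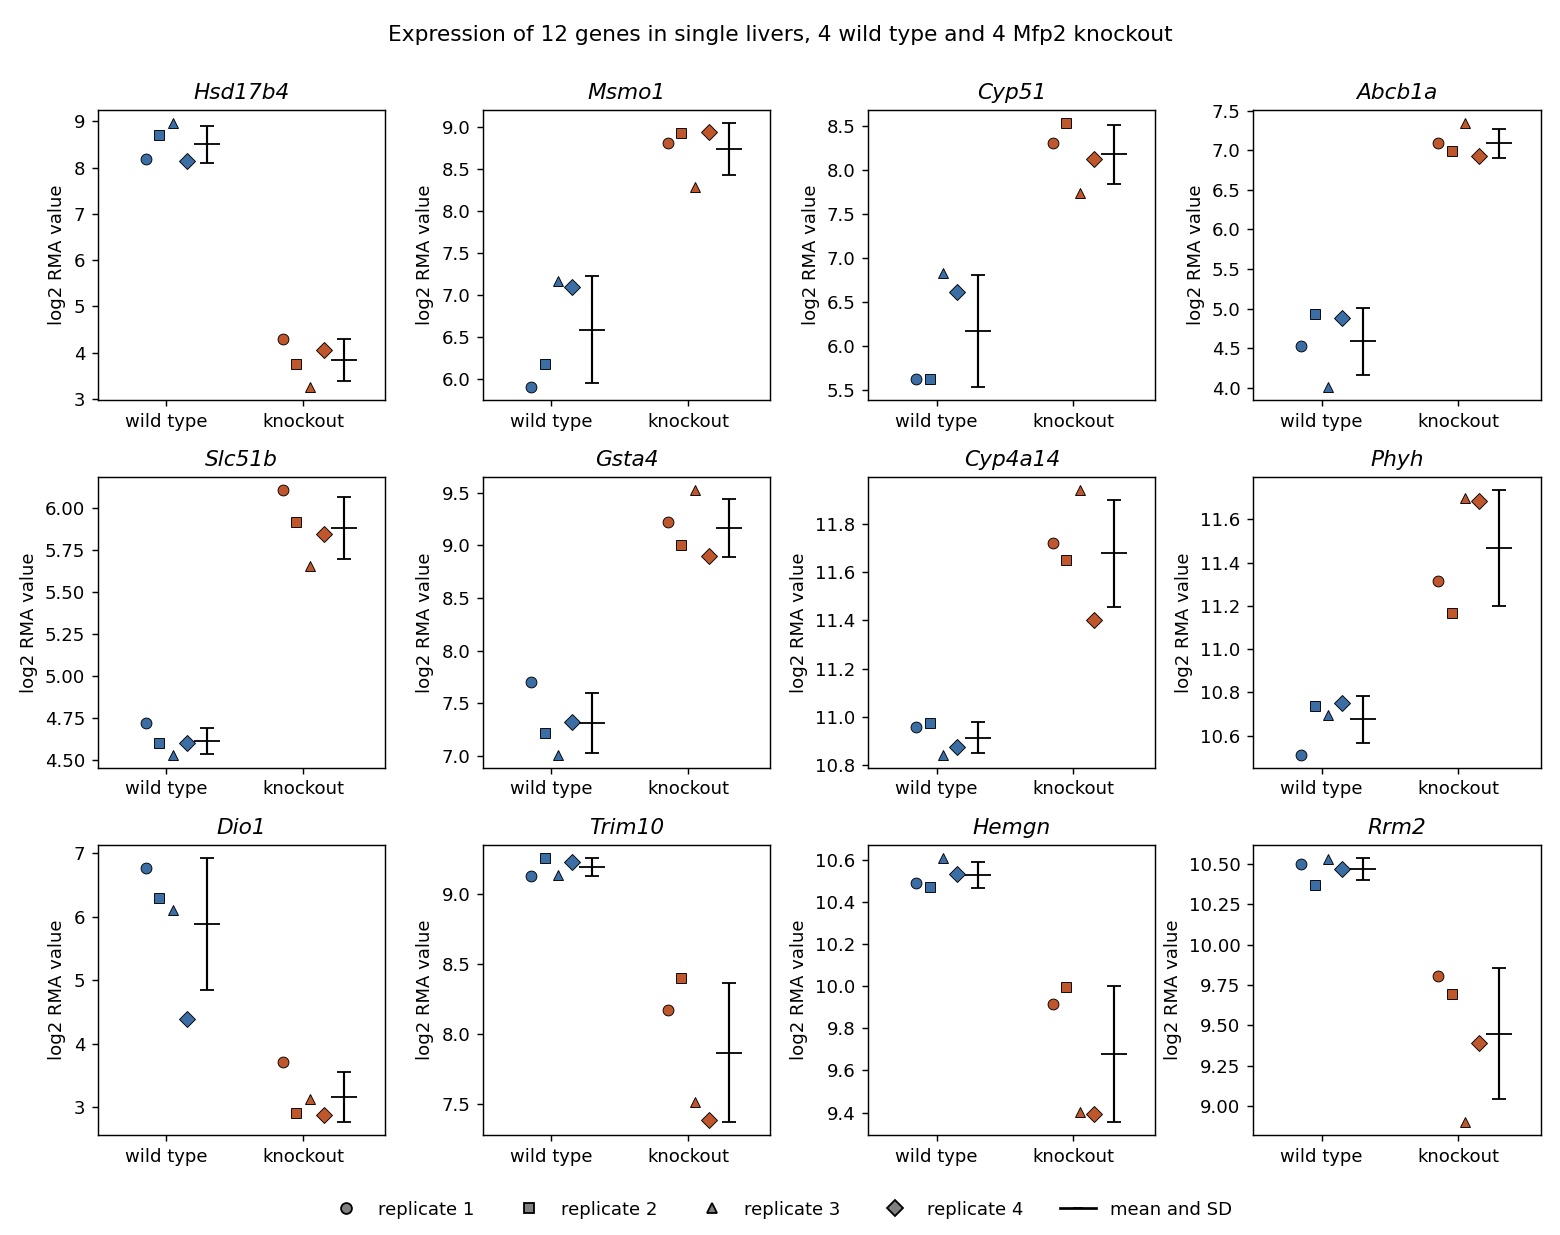
Log2 RMA values (y axis, its own range per gene) of 12 genes in the 4 wild type (blue) and 4 knockout (orange) livers, with marker shapes for the replicate numbers and a bar for the mean and SD of each group. Hsd17b4 averages 8.50 in wild type and 3.84 in knockout livers, and in each of the 12 panels the groups do not overlap.

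All 20 measured members of the list of SREBP2 targets for cholesterol synthesis and uptake had higher means in the knockout. Of these, 10 passed over all probe sets and 15 adjusted over the list alone, with 0 lower by either count. Msmo1 rose by 2.16 ± 0.29 (SE), a 4.46-fold change, and Cyp51 by 2.01 ± 0.29 and both act on the methyl groups of lanosterol-type sterols. Fdps, which makes farnesyl diphosphate, rose by 1.63 ± 0.28, and Lss, which closes the sterol ring, by 1.62 ± 0.22. The regulator Srebf2 itself differed by 0.16 ± 0.13, with an adjusted p of 0.721, a gene chosen after its values were seen. The median difference of the list was 1.14, or 2.21-fold, with a camera adjusted p of 7.6e-21 at the preset correlation and an adjusted p = 0.0951 with an estimated correlation. The mean of the list was 8.06 ± 0.18 (SD, n = 4) in knockout and 7.02 ± 0.32 in wild type livers. The median was 1.45 within replicates 1 and 2 and 0.81 within replicates 3 and 4. Left out singly, knockout 4 or wild type 4 took the count of 10 to 0, wild type 3 to 2, knockout 1 to 3, and knockout 2 or knockout 3 to 5, while the count adjusted over the list alone stayed at 15 or 16. The list was chosen with the known sterol theme of this knockout in mind, so its direction is not independent evidence.

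Target genes of PPARalpha, the nuclear receptor that senses fatty acids, were higher as a group. Of 39 measured targets, 33 had higher means. Cyp4a14, a fatty acid omega-hydroxylase, was the 1 that passed over all probe sets, with a rise of 0.76 ± 0.12 (SE), while 21 were higher and 2 lower adjusted over the list alone. The median difference was 0.50, with a camera adjusted p of 8.2e-13 and an adjusted p = 0.114 with an estimated correlation. It was 0.36 within replicates 1 and 2 and 0.47 within replicates 3 and 4. The single call on Cyp4a14 was lost without any 1 array but knockout 2 or wild type 2, and without wild type 2 the count was 6. In the list of peroxisomal lipid oxidation, which shares members with that of PPARalpha, 3 of 27 measured genes rose over all probe sets and 10 adjusted over the list alone. These 3 were Abcd2, a peroxisomal fatty acid transporter, by 0.80 ± 0.13, Phyh, which starts the alpha-oxidation of phytanic acid, by 0.79 ± 0.14, and Acaa1a, a peroxisomal thiolase, by 0.56 ± 0.11. The median was 0.36, with a camera adjusted p of 1.7e-06 and an adjusted p = 0.0837 with an estimated correlation, and it was 0.36 within each set of arrays. The 3 calls fell to 0 without knockout 3, knockout 4, wild type 1, wild type 3 or wild type 4, to 1 without knockout 1 and to 2 without knockout 2. Both lists were chosen from what is known of this knockout, and their counts are not independent evidence.

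The 19 measured genes of mitochondrial fatty acid oxidation had a median of 0.29, with 0 past the threshold over all probe sets in limma and 6 higher adjusted over the list alone, and a camera adjusted p of 3.3e-07, or adjusted p = 0.101 with an estimated correlation. The median was 0.25 within replicates 1 and 2 and 0.30 within replicates 3 and 4. Eci1, an enoyl-CoA isomerase, had the lowest p, with a difference of 0.63 ± 0.16 (SE) and an adjusted p of 0.116. The 9 genes of microsomal omega-oxidation had a median of 0.38, with a camera adjusted p of 0.00666, or adjusted p = 0.183 with an estimated correlation, and medians of 0.34 within replicates 1 and 2 and 0.54 within replicates 3 and 4. Cyp4a14 alone rose over all probe sets, and 5 were higher and 1 lower adjusted over the list alone, a count of 5 that was 3 without knockout 1, 2 or 3 or without wild type 3 or 4. Acyl-CoA thioesterases did not pass as a list, with a camera adjusted p of 0.189, 4 higher and 2 lower of 12 adjusted over the list alone, and a difference of 0.99 ± 0.20 in Acot2 (adjusted p 0.0583). Peroxisome assembly genes had a median of 0.15 over 13 genes, with 0 past the threshold by either count, a camera adjusted p of 0.0281 and adjusted p = 0.3003 with an estimated correlation. Pex11a, with the lowest p among them, differed by 0.79 ± 0.30 (adjusted p 0.328). The assembly call was lost without knockout 3, with a median of 0.09 and an adjusted p of 0.199, without wild type 1, at an adjusted p of 0.133, and within replicates 1 and 2, with a median of 0.07 and an adjusted p of 0.157, against a median of 0.24 within replicates 3 and 4. Ether lipid synthesis did not pass, with a camera adjusted p of 0.919 over 8 genes, 1 higher adjusted over the list alone, and a difference of 0.52 ± 0.15 in Cept1 (adjusted p 0.167). Of the 4 genes of the ketone body synthesis list 2 were found by symbol, too few for a test, with Acat1 at -0.28 ± 0.13 (adjusted p 0.448).

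In the list of bile acid and sterol transport 3 of 18 genes rose over all probe sets, and 6 were higher and 1 lower adjusted over the list alone. They were Abcb1a, Slc51b and Abcb11, the canalicular bile salt export pump, which rose by 0.97 ± 0.17 (SE). The list's median was 0.18, with a camera adjusted p of 0.000346, or adjusted p = 0.101 with an estimated correlation, and it was 0.24 within each set of arrays. The calls fell from 3 to 2 without knockout 1, 2, 3 or 4 or without wild type 1, 3 or 4, and numbered 5 without wild type 2, where the median was 0.28. In bile acid synthesis and conjugation 2 of 15 genes rose over all probe sets, Slc27a5, which activates bile acids for conjugation, by 0.78 ± 0.12, and Akr1d1, a reductase of the steroid ring, by 0.69 ± 0.12. Adjusted over the list alone 4 were higher and 1 was lower. The lower one was Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at -0.65 ± 0.19 (adjusted p 0.189 over all probe sets), chosen after its values were seen. The median was 0.37, with a camera adjusted p of 0.00672, or adjusted p = 0.103 with an estimated correlation, and it was 0.06 within replicates 1 and 2 and 0.40 within replicates 3 and 4. Without knockout 1, 2, 3 or 4 or without wild type 3 or 4, 0 of these genes passed, and without wild type 1 a single gene did.

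Of 16 genes of the NRF2 oxidative stress response 3 rose over all probe sets and 6 adjusted over the list alone. These were Gsta4, by 1.85 ± 0.17 (SE), Osgin1, by 1.19 ± 0.17, and Ephx1, the microsomal epoxide hydrolase, by 0.94 ± 0.17. The median was 0.55, with a camera adjusted p of 2.6e-08 and an adjusted p = 0.139 with an estimated correlation. It was 0.43 within replicates 1 and 2 and 0.85 within replicates 3 and 4. Knockout 3 stood apart, with a list mean of 8.49 against 7.40 to 7.52 in the other knockout livers and 6.86 to 7.04 in wild type livers, and without it the median was 0.31. The 3 calls fell to 1 without knockout 3, knockout 4, wild type 3 or wild type 4, and to 2 without any other array. Of 16 target genes of the xenobiotic receptors CAR and PXR, Cyp2c55, a cytochrome P450, rose over all probe sets, by 1.09 ± 0.16 from 2.83 ± 0.19 (SD, n = 4), and 9 were higher adjusted over the list alone. That wild type mean lies below the median of each array, and the knockout mean of 3.92 ± 0.32 lies near those medians. Neither mean is shown to be above background, so expression of Cyp2c55 is not shown and the size of its rise is uncertain. The call on Cyp2c55 was lost without knockout 3 or 4 or without wild type 1, 3 or 4, and the count of 9 was 3 without wild type 3, 4 without knockout 1, and 5 without knockout 3 or without wild type 1. The median was 0.63, with a camera adjusted p of 2.1e-06, or adjusted p = 0.0951 with an estimated correlation, and it was 0.49 within replicates 1 and 2 and 0.56 within replicates 3 and 4. The list means per liver overlapped between the groups, with an exact permutation p = 0.0857. The members Cyp2b10 and Cyp3a11 were at -0.02 ± 0.19 and 0.18 ± 0.16 (limma adjusted p 0.985 and 0.753). They were named after their values were seen.

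Of 13 genes of glycolysis and glycogen, Hk1, a hexokinase, fell over all probe sets, by 0.75 ± 0.13 (SE), and 3 were lower adjusted over the list alone. The median was -0.25, with a camera adjusted p of 0.000288 and an adjusted p = 0.0951 with an estimated correlation, and it was -0.35 within replicates 1 and 2 and -0.15 within replicates 3 and 4. Hk1 still passed without knockout 1 but not without any of the other 7 arrays. Adjusted over the list alone 7 were lower without knockout 4. The list means of glycolysis and of erythroid markers both parted the groups, lower in the knockout, and with the erythroid mean as a covariate the glycolysis median was -0.51 (adjusted p 0.000304), in a fit where that mean is nearly confounded with genotype. The SREBP1c targets for fatty acid and triglyceride synthesis had a median of 0.29 over 21 genes, with 0 past the threshold over all probe sets and 10 higher and 3 lower adjusted over the list alone. The 3 lower were Srebf1, the regulator's own gene, at -0.46 ± 0.15, Pklr at -0.94 ± 0.27 and Pnpla3 at -0.43 ± 0.16. They were named after their values were seen, with limma adjusted p between 0.171 and 0.326 over all probe sets. Fasn, the fatty acid synthase, had the lowest p, with a difference of 0.62 ± 0.15 (adjusted p 0.0998). Their camera adjusted p was 0.00152, or adjusted p = 0.139 with an estimated correlation. The median was 0.38 within replicates 1 and 2 and 0.18 within replicates 3 and 4, where the list did not pass, at an adjusted p of 0.140. Gluconeogenesis and the fasting response did not pass, with a camera adjusted p of 0.235 over 9 genes, 0 of them past the threshold and 1 lower adjusted over the list alone. Its median was -0.23 (adjusted p 0.0288) within replicates 1 and 2 and 0.65 (adjusted p 0.00138) within replicates 3 and 4, opposite in sign, where genotype in replicates 1 and 2 goes with sex. Fbp1, a gluconeogenic phosphatase, was at -0.56 ± 0.11 (adjusted p 0.0592).

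**Figure D2:**
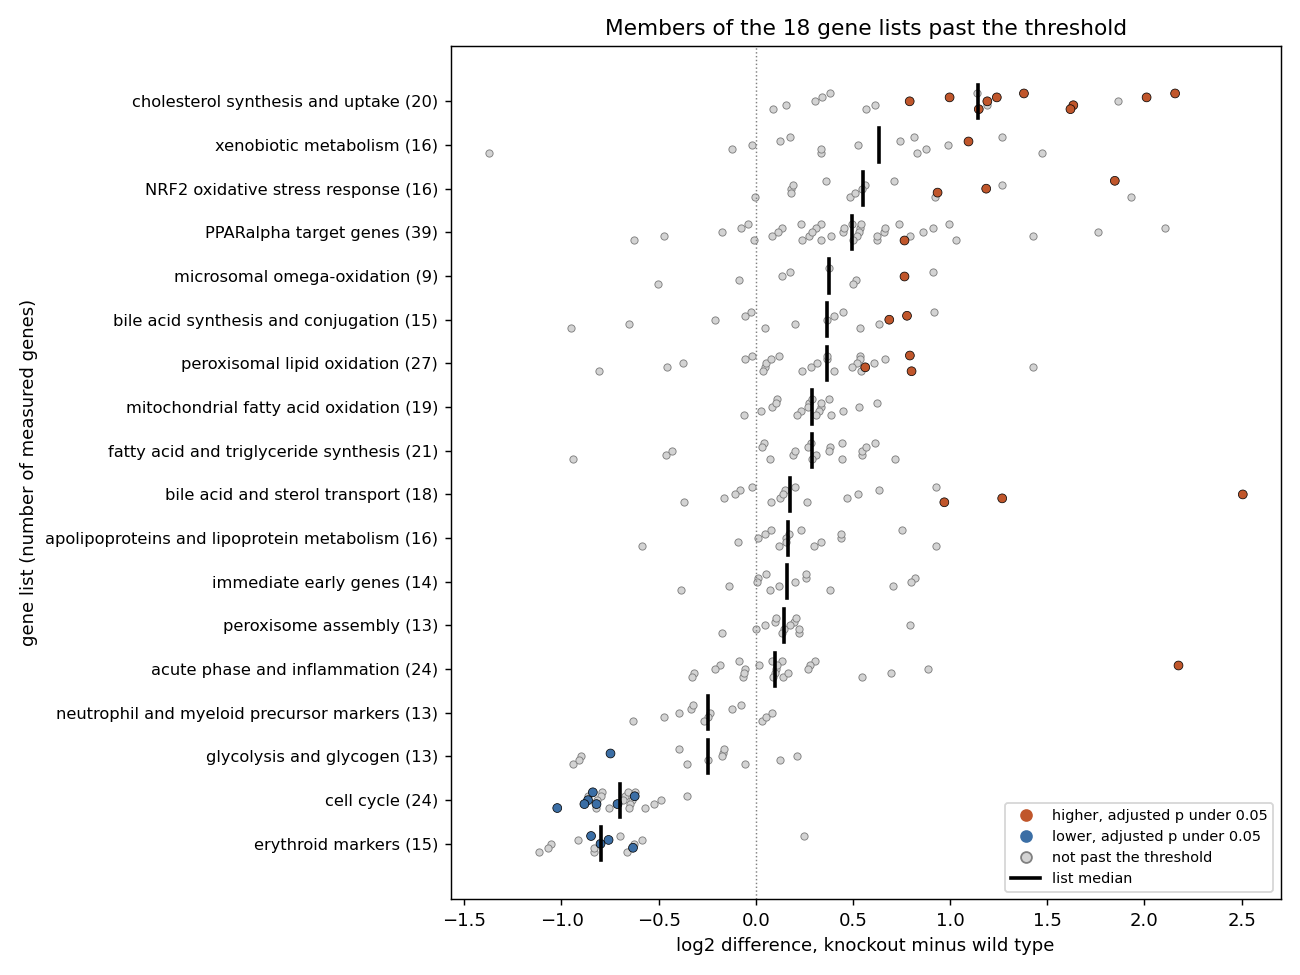
Log2 differences, knockout minus wild type (x axis), of the measured members of the 18 gene lists past the camera threshold (y axis, number of members in brackets), with orange and blue points for members past the limma threshold, grey points for the others and a black bar for the list median. Medians run from -0.80 for erythroid markers to 1.14 for cholesterol synthesis and uptake.

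Cell cycle genes were lower as a block. All 24 measured members had lower means in the knockout, 7 fell over all probe sets, and 22 were lower adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, fell by 1.02 ± 0.18 (SE), Ube2c by 0.88 ± 0.16, Birc5 by 0.86 ± 0.15 and the mitotic kinase Plk1 by 0.84 ± 0.12. The median was -0.70, a 1.62-fold lower level, with a camera adjusted p of 1.0e-25 and an adjusted p = 0.0951 with an estimated correlation. It was -0.52 within replicates 1 and 2 and -0.94 within replicates 3 and 4. The count of 7 fell to 0 without knockout 3, knockout 4, wild type 3 or wild type 4, to 2 without wild type 1 and to 4 without knockout 1, and was 13 without wild type 2, while 22 or 23 members were lower adjusted over the list alone in each of these fits.

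Markers of red blood cell precursors fell together with the cell cycle genes. Of 15 measured erythroid markers 14 had lower means, 4 fell over all probe sets and 14 adjusted over the list alone. Hemgn, an erythroid nuclear protein, fell by 0.85 ± 0.15 (SE), Rhag by 0.80 ± 0.15, Ermap, a red cell membrane protein, by 0.76 ± 0.12, and Cpox, an enzyme of heme synthesis, by 0.63 ± 0.11. The exception, Hba-a1, was read near the bottom of the scale, at 2.14 in knockout and 1.90 in wild type livers, and was named after its values were seen. The median was -0.80, with a camera adjusted p of 5.2e-15 and an adjusted p = 0.101 with an estimated correlation. It was -0.49 within replicates 1 and 2 and -1.003 within replicates 3 and 4. The marker mean lay between 7.81 and 8.48 in the knockout and between 8.81 and 8.96 in the wild type livers. The count of 4 fell to 0 without knockout 3, knockout 4, wild type 3 or wild type 4 and to 1 without wild type 1, and was 9 without knockout 2, while 14 were lower adjusted over the list alone in each of these fits. This mean parted the groups, as did the means of all other lists with the smallest exact permutation p (13 with this one), so over the livers it went with them. They are the lists of cholesterol synthesis, PPARalpha, SREBP1c and NRF2 targets, peroxisomal, mitochondrial and omega-oxidation, thioesterases, bile acid transport, glycolysis, cell cycle and the circadian clock. Hepatocyte markers had a median of 0.12 over 11 genes and did not pass, with a camera adjusted p of 0.189. Fgb, a fibrinogen chain, was at 0.31 ± 0.09 (adjusted p 0.187).

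**Figure D3:**
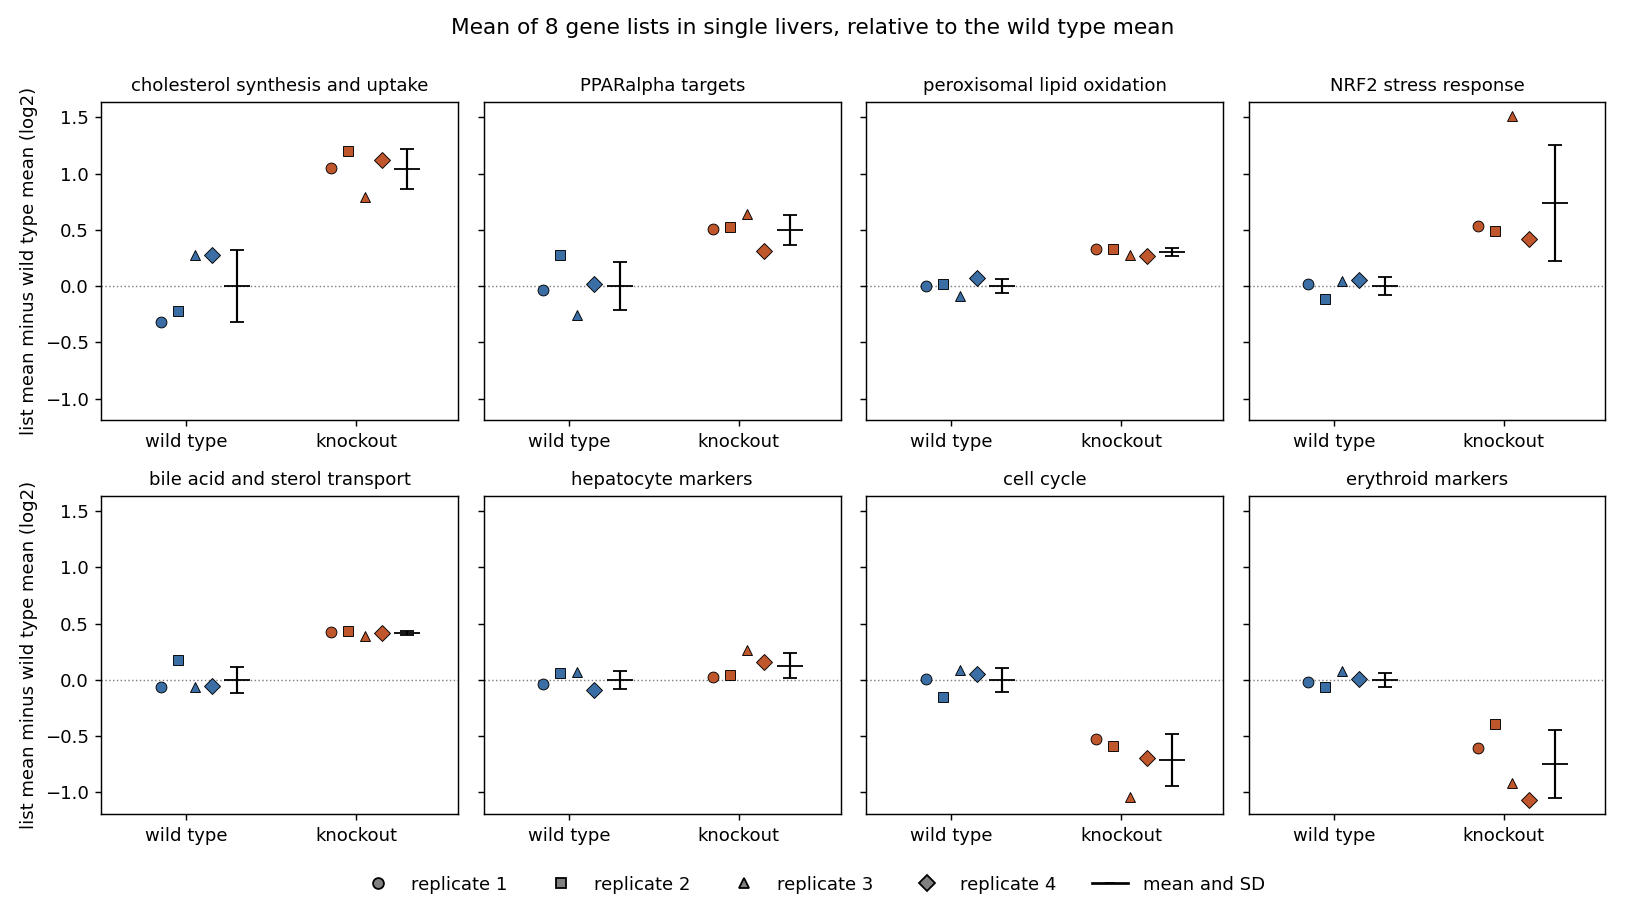
Mean of 8 gene lists in each liver minus the mean of the 4 wild type livers (y axis, log2), for wild type (blue) and knockout (orange) livers, with marker shapes for the replicate numbers and a bar for the mean and SD. Erythroid means lie between 7.81 and 8.48 in knockout and between 8.81 and 8.96 in wild type livers before this subtraction, and knockout 3 stands above the other livers in the NRF2 list.

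Neutrophil and myeloid precursor markers had a median of -0.24 over 13 genes, with 0 past the threshold by either count. Their camera adjusted p was 0.0266 and adjusted p = 0.664 with an estimated correlation, and the call was lost without knockout 1, 2 or 3 or without wild type 2, with a highest adjusted p of 0.257 and a median of -0.11 without wild type 2. The median was -0.60 (adjusted p 1.9e-10) within replicates 1 and 2 and 0.01 (adjusted p 0.320) within replicates 3 and 4, so lower values were seen in 1 of the 2 sets of arrays, the one where genotype goes with sex. Ltf, a granule protein, was at -0.47 ± 0.22 (SE; adjusted p 0.452). Lists of 8 other cell types or tissues did not pass, with 0 members past the threshold by either count. Their camera adjusted p was 0.895 for megakaryocytes and platelets, 0.389 for Kupffer cells and macrophages, 0.318 for lymphocytes, 0.382 for sinusoidal endothelium, 0.345 for stellate cells and fibroblasts, 0.0841 for cholangiocytes, 0.430 for pancreas and 0.874 for skeletal muscle. The members with the lowest p were Itga2b at 0.20 ± 0.10, Mpeg1 at 0.42 ± 0.17, Vpreb1 at -0.68 ± 0.22, Lyve1 at 0.61 ± 0.30, Ecm1 at 0.34 ± 0.17, Cldn7 at 0.96 ± 0.32, Cpa1 at 0.22 ± 0.11 and Mylpf at -0.19 ± 0.12, with adjusted p between 0.228 and 0.638. The cholangiocyte list passed as higher in 4 planned settings, at adjusted p 0.0312 with the filter on dim probe sets (median 0.62), 0.0309 with the Y-linked covariate, 0.0196 with the mean of all probe sets and 0.0124 without knockout 1. It also passed in livers with high Y-linked values (0.00952) and within replicates 3 and 4 (0.00996). Kupffer cell markers passed as higher with the erythroid covariate, with a median of 0.60 (adjusted p 0.00746). Without knockout 2 the endothelial and stellate cell lists passed as lower (0.0164 and 0.0144), as they did in livers with high Y-linked values (0.00824 and 0.0301), and with the erythroid covariate the endothelial list passed as higher (0.00981).

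Of the 38 tested lists 18 passed in camera at the preset correlation, 14 higher and 4 lower. With an estimated correlation 0 passed after adjustment, and 13 had an unadjusted p under 0.05. In the exact permutation test of list means per liver 13 of the 38 reached the smallest p that 4 against 4 livers allow, 0.0286, which is 0.0835 after adjustment over the 38. Of the 18 lists past the camera threshold 11 reached it. The other 7 had an exact permutation p of 0.314 for neutrophil markers, 0.143 for acute phase, 0.0857 for peroxisome assembly and xenobiotic metabolism, and 0.0571 for bile acid synthesis, apolipoproteins and immediate early genes. The median and the mean difference of a list had opposite signs in ether lipid synthesis, at -0.023 and 0.0094, and in megakaryocyte markers, at 0.0013 and -0.0084.

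Genes near the targeted gene were examined because DNA from the embryonic stem cells used for targeting can stay linked to it. Within 20 Mb of Hsd17b4 on chromosome 18, 5 of 288 genes passed the threshold, or 1.74%, against 1.14% of all other genes with a position. The odds ratio was 1.53 (95% interval 0.487 to 3.66, Fisher's exact test, two-sided p = 0.392). The 5 genes were Slc4a9 and Tmco6, higher, and Kif20a, Cep76 and Slc23a1, lower in the knockout. Without knockout 3, knockout 4, wild type 3 or wild type 4, 0 genes there passed. Without knockout 1 the odds ratio was 3.06, with an exact two-sided p = 0.0286.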

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

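The comparisons with other hepatocyte genes and the tests on the 2 sets of arrays were chosen after the results they bear on were seen. A sample was singled out where its distance to the nearest of the other 3 in its group, divided by the range of the group, exceeded Dixon's 95% critical value. This was met in 15 of 216 groups of 4, where chance gives about 10.8.

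Knockout 1 lay apart in 6 named genes. Its log2 value was 4.87 in Dscc1, against 3.90 to 4.03 in the other knockout livers, and 8.42 in Abcd2, against 8.75 to 8.79. It was 9.11 in Eci1, against 9.54 to 9.58, and 8.93 in Akr1d1, against 8.73 to 8.75. It was 4.40 in Cyp2c55, against 3.75 to 3.77, and 8.33 in Cpox, against 7.94 to 7.98. Knockout 2 lay apart in Hbb-bh1 at 4.95, against 4.27 to 4.36, in Vpreb1 at 3.14, against 3.72 to 3.84, and in the mean of the apolipoprotein list at 10.7, against 10.84 to 10.86. Knockout 3 lay apart in Nr1d2 at 8.42, against 7.28 to 7.45, in Zfp36 at 8.02, against 7.08 to 7.24, and in the mean of the NRF2 list at 8.49, against 7.40 to 7.52. Wild type 2 lay apart in Birc5 at 8.76, against 9.30 to 9.35, in the mean of the bile acid and sterol transport list at 6.79, against 6.55 to 6.56, and in the mean of the stellate cell list at 6.99, against 6.84 to 6.85.

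The lists of erythroid markers and cell cycle genes had lower means together in the knockout livers. Both calls in camera were lost with an estimated correlation (adjusted p 0.101 and 0.0951). With the Y-linked mean as a covariate the medians were -0.85 and -0.72, so the sex make-up of the groups does not account for them, and without each array in turn they came no nearer to 0 than -0.69 and -0.61, so no single array does. Whether fewer dividing red cell precursors may lie behind the cell cycle genes stays open, since over the 8 livers the deviations of both means from their group means correlated with r = 0.58 (exact permutation p = 0.314) and Spearman's rho = 0.833 (exact permutation p = 0.0556). Without knockout 2 and knockout 4, the 2 livers whose erythroid means deviated most from their group mean, r was 0.969. That value was not tested and leaves 2 knockout livers. With the erythroid mean as a covariate, which is nearly confounded with genotype (variance inflation 4.83), the cell cycle median went from -0.70 to -0.38 (camera adjusted p 1.9e-05), and a lower rate of division of other liver cells was not tested.

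The lists of cholesterol synthesis genes and of PPARalpha targets had higher means in the knockout livers. Both calls in camera were lost with an estimated correlation (adjusted p 0.0951 and 0.114). With the Y-linked mean as a covariate the medians were 1.09 and 0.50, which argues against the sex make-up. A smaller share of erythroid cells would raise hepatocyte transcripts alike. The comparison was with 26 genes of the hepatocyte marker list and of the amino acid catabolism and urea cycle list. Relative to them the cholesterol and PPARalpha lists still rose by 0.95 ± 0.25 (SE) and 0.40 ± 0.12. Each had an exact permutation p of 0.0286, the smallest that 4 against 4 livers allow. An effect of the lost enzyme on cholesterol synthesis genes and PPARalpha targets is a hypothesis that may account for both rises. Other differences between the mice, such as feeding, stay open as untested.

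The arrays of replicates 1 and 2 differed from those of replicates 3 and 4 at 170 probe sets, 154 of them higher in replicates 3 and 4, and 0 of these were among the calls between genotypes. Among the 12 with a gene name and the lowest p, shifts were 3.38 in a probe set of Wnk1, 3.31 in Rufy3, 3.29 in Kcnq1ot1 and 3.15 in Cbl. For 104 of the 142 probe sets with a gene name another probe set of the gene was brighter. These brighter probe sets shifted by a median of 0.13 where the called ones, picked for a large shift, shifted by 1.12. That argues against changed levels of whole mRNAs for the genes of these 104. The comparison does not cover calls at the brightest probe set of a gene, seen for 38 genes. The 3' minus 5' value of the actin control differed by 0.0165 ± 0.0777 (SE; exact permutation p = 0.914), which argues against RNA degradation. A difference between labelling or hybridization batches may remain, and no label gives one.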

How the results depend on the processing

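The settings that split the livers by sex-chromosome pattern or by replicates 1 and 2 against 3 and 4 were chosen after seeing the data. In replicates 1 and 2 alone genotype cannot be told apart from sex, since both knockout livers and neither wild type liver were high in Xist. The 209 genes past the threshold kept their direction in all settings in which they were measured. Where livers were only left out this was given in advance, since the groups of these genes did not overlap. A sign change of a value past no threshold was seen 65 times over 26 alternatives and is not counted as a reversal.

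The number of calls depended on the setting. Beside 343 probe sets and 209 genes (56 higher, 153 lower), array weights gave 914 probe sets and 545 genes (152 higher, 393 lower), and the Y-linked mean as a covariate gave 527 and 320, 247 of them lower. The mean of all probe sets gave 383 genes (97 higher, 286 lower), and quantile normalization again gave 137, 92 of them lower. An adjusted p under 0.01 left 8 probe sets and 4 genes (3 higher, 1 lower). Without single arrays the calls ranged from 9 to 489 probe sets, from 5 to 286 genes, from 3 to 79 higher and from 1 to 207 lower genes. In replicates 1 and 2 alone there were 4 probe sets and 3 genes (2 higher, 1 lower), and in livers with high Y-linked values (2 knockout, 3 wild type) there were 43 and 29 (4 higher, 25 lower).

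In 2 settings limma called 0 probe sets and 0 genes, 0 higher and 0 lower. In livers with high Xist, where the single wild type liver is assumed to vary like the others, 3603 probe sets had an unadjusted p under 0.05 and the difference in Hsd17b4 was -4.94. With the erythroid marker mean as a covariate, 2216 had one. This mean is nearly confounded with genotype (variance inflation 4.83). The difference in Hsd17b4 went from -4.66 to -4.41 while its SE went from 0.247 to 0.564, so its call ended because the error grew (unadjusted p 2.85e-05 in limma). The median SE ratio was 2.26.

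The values showed no clear pairing of livers by replicate number, though so few livers cannot exclude shared litters or processing. The deviations of same-numbered livers from their group means correlated at -0.0039, 0.0689, 0.174 and 0.259, and only in replicate 4 did both livers correlate best with their own number. With the replicate block 15 probe sets and 9 genes passed (5 higher, 4 lower), 8 of them shared with the 209 genes, and 0 members of the cholesterol, cell cycle and erythroid lists.

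The 10 cholesterol genes called over all probe sets were 0 with the erythroid covariate, at an adjusted p under 0.01, in livers with high Y-linked values and in those with high Xist, 2 in each set of arrays alone, and 0 to 8 without single arrays. With the erythroid covariate the median of the list went from 1.14 to 1.365 (camera adjusted p 6.5e-18), so the list median did not shrink where the calls were lost. The 7 cell cycle calls were 17 with array weights, 14 with the mean of all probe sets, 13 with the filter or the Y-linked covariate, 4 with quantile normalization again, 0 to 13 without single arrays, and 0 with the erythroid covariate, at an adjusted p under 0.01, in both sex-pattern settings and in replicates 1 and 2 alone. Adjusted over the list alone they were 0 with the erythroid covariate and in replicates 1 and 2 alone. The 4 erythroid calls were 13 with array weights, 9 with the Y-linked covariate and in replicates 3 and 4 alone, 8 with the mean of all probe sets and with the 2 sets of arrays as a block, 7 with the filter, 2 in livers with high Y-linked values, 1 with quantile normalization again and 0 to 9 without single arrays. They were 0 with the erythroid covariate, at an adjusted p under 0.01, in livers with high Xist and in replicates 1 and 2 alone. In these settings but the stricter p, they were also 0 adjusted over the list alone.

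With an estimated correlation in camera none of the 18 lists passed. The adjusted p was 0.0837 for peroxisomal lipid oxidation, 0.0951 for cholesterol synthesis, glycolysis, xenobiotic metabolism, apolipoproteins and cell cycle, 0.101 for mitochondrial oxidation, bile acid transport and erythroid markers, and 0.103 for bile acid synthesis. It was 0.114 for PPARalpha targets, 0.139 for SREBP1c targets and NRF2, 0.183 for omega-oxidation, 0.234 for acute phase, 0.3003 for peroxisome assembly, 0.341 for immediate early genes and 0.664 for neutrophil markers. At an unadjusted p under 0.05 there were 13 lists.

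Of the other camera settings, 13 of the 18 lists passed in all but the erythroid covariate for its own list (adjusted p 0.8294) and replicates 3 and 4 alone for SREBP1c targets (0.140). Peroxisome assembly had an adjusted p of 0.0713 with array weights, 0.410 in livers with high Xist, 0.157 in replicates 1 and 2 alone, 0.0109 to 0.199 without single arrays, and with the erythroid covariate its direction in camera reversed at 0.954. Acute phase genes had 0.172 in livers with high Xist, 0.157 in replicates 1 and 2, 0.00467 to 0.0922 without single arrays, and with the erythroid covariate camera's direction reversed at 0.919 while the median stayed at 0.09. Apolipoproteins had 0.445 with the erythroid covariate, 0.103 in livers with high Xist and 0.0748 in replicates 1 and 2. Immediate early genes had 0.0775 with array weights, 0.231 with the erythroid and 0.0523 with the Y-linked covariate, 0.0580 with the mean of all probe sets, 0.461 in livers with high Xist, 0.101 in replicates 1 and 2, and 0.0211 to 0.166 without single arrays. Neutrophil markers had 2.9e-11 with the erythroid covariate, where their median went from -0.24 to -0.83, 0.0751 with the filter, 0.383 with array weights, 0.119 with the Y-linked covariate, 0.410 and 0.234 in livers with high Y-linked values and with high Xist, 2.3e-05 to 0.257 without single arrays, and camera's direction reversed in replicates 3 and 4 alone at 0.320 with a median of 0.01.

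Among lists that did not pass, 2 passed in the opposite direction elsewhere: gluconeogenesis at 0.0152 with the erythroid covariate and 0.0288 in replicates 1 and 2 alone, and sinusoidal endothelium at 0.00981 with the erythroid covariate. Others passed in their own direction. Without knockout 2 gluconeogenesis (0.0382) and amino acid catabolism (0.0354) passed as higher, as they did in livers with high Y-linked values (0.00410 and 0.00573) and in replicates 3 and 4 alone (0.00138 and 0.0122). Endoplasmic reticulum stress genes (0.0389) and hepatocyte markers (0.0229) passed as higher in livers with high Y-linked values, and acyl-CoA thioesterases in those with high Xist (0.00626). The odds ratio near the targeted gene was 2.03 (p = 0.0385, Fisher's exact test) with the Y-linked covariate, and 0 to 3.06 without single arrays. The causes of these changes were not tested beyond the values given. Dim probe sets near the bottom of the scale, such as those of Hba-a1, limit what can be read for their genes.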

Other observations

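The tests of the splits, of thyroid hormone targets and of genes near Hsd17b4 were set out before their results were seen, while the fits within or blocked by replicates 1 and 2 against 3 and 4 were chosen after seeing the data. Within replicates 1 and 2 genotype cannot be told apart from sex.

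Further lists passed as higher in camera at the preset correlation and not with an estimated one. The apolipoprotein and lipoprotein list had a median of 0.16 over 16 genes, with 0 past the threshold over all probe sets and 2 higher adjusted over the list alone, and a camera adjusted p of 0.00152, or adjusted p = 0.0951 with an estimated correlation. The median was 0.08 within replicates 1 and 2 and 0.27 within replicates 3 and 4. Lpl, which releases fatty acids from lipoproteins, was at 0.44 ± 0.09 (SE; adjusted p 0.0636) and also had the lowest p among LXR targets, a list that did not pass (camera adjusted p 0.430 over 9 genes, 1 higher adjusted over the list alone). The acute phase and inflammation list had a median of 0.10 over 24 genes and a camera adjusted p of 0.0195, or adjusted p = 0.234 with an estimated correlation, with medians of 0.11 within replicates 1 and 2 and 0.17 within replicates 3 and 4. Cxcl10 alone rose over all probe sets, and 4 genes were higher adjusted over the list alone, or 1 without knockout 1, 3 or 4 or without wild type 3 or 4 and 2 without wild type 1. The list did not pass without knockout 4 (adjusted p 0.0583) or wild type 1 (0.0922), and its median was 0.16 without wild type 2. Immediate early genes had a median of 0.16 over 14 genes, a camera adjusted p of 0.0480, or adjusted p = 0.341 with an estimated correlation, 0 past the threshold and 1 higher adjusted over the list alone, with Zfp36 at 0.80 ± 0.20 (adjusted p 0.123). Their median was 0.06 within replicates 1 and 2 and 0.26 within replicates 3 and 4, and the list did not pass without knockout 2 or 3 or without wild type 2 or 4, with a median of 0.05 without knockout 3 and 0.08 without wild type 2.

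Other lists did not pass in camera with all arrays and the planned fit. In the p53 response and cell death list (13 genes, camera adjusted p 0.748) Gadd45a fell by 0.98 ± 0.14 (SE) and Gadd45b rose by 0.81 ± 0.15. These related stress-response genes passed in limma over all probe sets and adjusted over the list alone. In the endoplasmic reticulum and integrated stress list (23 genes, 0.430) Asns, the asparagine synthetase, fell by 0.52 ± 0.10 and was lower adjusted over the list alone. In the fetal liver list (10 genes, 0.430) Hbb-bh1 alone passed, by both counts. In lipid droplet and lipolysis genes (15 genes, 0.402) 2 were lower adjusted over the list alone, with G0s2, an inhibitor of lipolysis, at -1.08 ± 0.23 (adjusted p 0.0757). Circadian clock genes (16 genes, 0.0591) had 3 higher adjusted over the list alone and Nr1d2 at 0.90 ± 0.24 (adjusted p 0.136). The clock list passed as higher with median centring (0.0498), without knockout 2 (0.0354) or knockout 4 (0.0439) and without wild type 2 (0.0486). Growth hormone and IGF genes (12 genes, 0.748) had 1 higher and 1 lower adjusted over the list alone and Igfals at -0.39 ± 0.11 (adjusted p 0.145). Amino acid catabolism and urea cycle genes (18 genes, 0.296) had 0 past the threshold by either count and Asl at 0.56 ± 0.22 (adjusted p 0.341).

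Of the 35 splits of the 8 livers into 4 and 4, 1 gave as many probe sets as the genotypes, the genotype split itself, with 343 against 170 in the highest other split, that of replicates 1 and 2 against 3 and 4. Likewise 1 of 35 gave as many genes, with 209 against 38. That is the smallest share the 35 splits allow, and it treats all livers as exchangeable, although the 2 sets of arrays differ. Of the 35 splits, 18 keep 2 livers of replicates 1 and 2 on each side. There 1 of 18 gave as many, the genotype split itself, and 18 splits are too few for a share under 0.05. The highest count in the other 17 was 0 probe sets and 0 genes. The genotype split thus exceeded all others, but chance is not excluded for either count. For the lists, 3 of 35 splits gave as many as 18 and the highest other gave 21, and of the 18 splits 2 gave as many, so chance cannot be excluded for the number of lists. With replicates 1 and 2 against 3 and 4 as a block 514 probe sets, 302 genes and 18 lists passed between the genotypes.

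Dio1 is itself induced by thyroid hormone, so its fall may come with lower thyroid hormone action in the knockout livers. This was a hypothesis tested on 8 other target genes, which had a median of 0.25 and a camera p of 0.0965 in the upward direction. Named after their values were seen, they were Me1 (0.55), Cpt1a (0.53), Klf9 (0.50), Bcl3 (0.40), Hr (0.10), Thrsp (0.04), Idh3a (-0.10) and Gpd2 (-0.96). Me1 and Thrsp are also in the SREBP1c list, Me1 in the NRF2 list and Cpt1a in the PPARalpha list, which were higher. The upward median is therefore not independent of those lists. The test did not decide the hypothesis, as the genes neither fell together nor passed as higher. Linked DNA of another strain may change genes near Hsd17b4, and the odds ratio of 1.53, with an interval from 0.487 to 3.66, leaves that open.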
